A study of Mus musculus with 7 samples.

How the data were processed

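Single-nucleus RNA libraries were made from the brains of 5xFAD mice, a transgenic line that forms amyloid plaques, carrying the transgenes on 1 chromosome copy (5xFAD +/-). Per the labels, the mice were 6 months old and had received an AAV vector by retro-orbital injection at 4 months, either a control AAV (3 mice) or an AAV for ANGPT2 (4 mice). ANGPT2 (angiopoietin-2) is a secreted ligand of the endothelial receptor TIE2, which the gene Tek encodes. By the labels the tissue was the subcortex, thalamus and hippocampus, and each library came from 1 mouse. The labels give the sex of each mouse and a batch (replicate 1 or 2). Batch 1 holds a male and a female of each group, and batch 2 holds a control male, an ANGPT2 male and an ANGPT2 female.

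The deposited matrices hold raw UMI counts per gene and barcode, with no normalization. Per the submitters' processing notes, the authors made them with Cell Ranger 6.1.2 on mm10 (GRCm38). The matrices list 32285 genes, of which 32158 have coordinates in GENCODE release M21, and 38 symbols belong to more than 1 gene identifier. The labels give 900 to 1500 nuclei loaded and name neither a volume nor a library for that number, while the matrices hold 6311 to 9630 barcodes per library. The 58286 barcodes were filtered on their own content and no number of nuclei was forced.

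A barcode was kept with at least 300 genes and under 5% of its UMIs from mitochondrial genes. This removed 1 barcode for too few genes and 116 for mitochondrial UMIs, and 58169 passed. Doublets were called per library from the share of simulated doublets among the 50 nearest neighbours (2 simulated doublets per nucleus, 2000 variable genes, 30 components), at a rate proportional to the library's number of nuclei. These calls covered 3939 nuclei (5.04% to 7.70% per library), which were removed after clusters were named, and 54230 were kept. The total UMIs of all barcodes ranged from 25466033 to 100529717 per library. The median UMIs per barcode were 7281.5, 8278, 6752 and 3678 in batch 1, and 2350.5, 2262 and 3407 in batch 2.

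The 58169 nuclei that passed, called doublets included, were clustered together after scaling to 10000 counts and taking logarithms, on 2500 variable genes chosen by their median rank over libraries. Mitochondrial and sex-linked genes were left out of this choice. Principal components (40) and a graph of 15 neighbours were used with the Leiden algorithm at resolution 1, which gave 42 clusters. Clusters were named from markers of 17 cell types that were written down before the data were examined. A name needed at least 3 detected markers, a marker score of at least 0.4 and a doublet share of at most 0.5. A cluster with median UMIs under 0.333 of the library's median also needed a marker of its own among its 10 leading genes. A cluster with more markers of another class than of its own among these 10 stayed unnamed too. These last 2 rules left clusters of 6748 and 1727 nuclei unnamed. Under these rules 6 clusters, with 5.80% to 30.1% of a library's nuclei, stayed unnamed and enter only the values of whole libraries. Dentate granule and thalamic neurons were merged with the other excitatory neurons for the tests, which left 13 classes. These other excitatory neurons made up 13.4% to 28.1% of a library's kept nuclei. Cux2 was among the leading genes of their cluster of 2865 nuclei, and Rorb among those of their cluster of 2789. The brain region that they came from was not tested. At this resolution no cluster was named for lymphocytes or for border macrophages, while at resolution 2, 1 cluster of 58 nuclei was named for lymphocytes.

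UMI counts were summed per library and class, and a library with fewer than 10 nuclei of a class was left out of that class. The groups were compared with edgeR 4.0.16 (quasi-likelihood test, TMM factors, treatment as the only term) on genes that passed filterByExpr (minimum count 10, minimum total 15). P-values were adjusted by the Benjamini-Hochberg method over the genes of the class, with a threshold of 0.05 on the adjusted p. Counts of genes at an unadjusted p under 0.05 are given as values only. With no difference between the groups and none between the batches, a share of about 0.05 of the tested genes would fall there by chance. All 7 libraries entered 1 fit per class. Gene-wise p-values and adjusted p-values come from edgeR unless DESeq2 is named. A log2 change is ANGPT2 over control. For some genes a value in each batch is also given, as a difference of mean log2 CPM. Standard errors (SE) come from the same fits as the log2 change.

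Gene lists (40) and the classes in which each was tested were fixed before the data were examined, as were the tests, the samples in them and most of the other settings tried. Lists with at least 5 tested genes were compared with camera at the preset correlation of 0.01, adjusted over all 96 list and class combinations. Each was repeated with a correlation estimated per list and with fry, which asks whether the members move on balance in 1 direction and sets no list against other genes. A list's score in a library is the mean log2 CPM of its members, and groups of scores were compared by a two-sided exact permutation test over the 35 splits of the 7 libraries. That test cannot give a p below 0.0286. Permuting only within batches leaves 18 arrangements and a smallest p of 0.0556. The lists for angiogenic sprouting, arterial endothelium, venous endothelium, smooth muscle contraction, A1 astrocytes, A2 astrocytes, red blood cells and peripheral leukocytes had too few tested genes for a test. Shares of nuclei per class were compared by the same exact test, adjusted over 13 classes. The treatment by sex interaction was tested with edgeR. It rests on 1 control female.

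The genes named in each class follow a rule set in advance. It takes the 10 genes per direction with the smallest p among those past the threshold or, where fewer than 5 passed in a direction, the 5 with the smallest p, given as values. It adds up to 4 members of each list and Angpt2, Tek, Tie1 and the sex-linked genes. Any other named gene is said to have been chosen after its values were seen.

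The labels do not pair mice across the groups, but the batch was tested as a possible block. After removal of group means, control and ANGPT2 libraries of the same batch had a mean correlation of 0.235 over whole libraries. Control and ANGPT2 libraries of different batches had one of -0.231. In astrocytes the corresponding values were 0.144 and -0.142, and in microglia 0.0629 and -0.0617. Removing the group means forces each second value to near minus the first, so only the first is informative. A fit with the replicate block was among the settings tried. It left 33 of 91 list and class combinations past the threshold, against 38 of 96 without the block.

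Other settings fixed in advance were sex as a covariate, block and sex together, males only, RLE size factors, no filter on low counts, at least 500 genes per nucleus, doublets kept, resolution 2 (63 clusters, of which 11 stayed unnamed), DESeq2 1.42.0, an edgeR test of nuclei per class, and leaving out each library in turn. Settings chosen after seeing the data left out certain neuron clusters, the control female of batch 1 or all unnamed nuclei, fitted the batch block to the males, thinned microglia to 270543 UMIs per library, removed microglia with markers of other immune cells, or fitted dentate granule, thalamic and other excitatory neurons apart.

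The tests were tried on simulated data built from the real counts. In endothelial nuclei edgeR recovered 18 of 100 genes changed 2-fold and 78 of 100 changed 4-fold, and in microglia 58 and 93. DESeq2 recovered 16 and 72 in endothelial nuclei and 41 and 91 in microglia. For edgeR the counts were 42 and 76 in mural nuclei, 56 and 91 in astrocytes, and 56 and 95 in oligodendrocytes, and it called 0 genes in data with no change. In the simulated data with changes edgeR also called 9 to 15 unchanged genes per class, and DESeq2 1 to 16. A simulated log2 change of -0.80 in a list of 17 genes gave a camera p of 1.1e-25, and 0.0012 with an estimated correlation. Of 200 random lists, 8 had an unadjusted p under 0.05 with the preset correlation and 2 with an estimated one. The simulated genes were drawn independently and without a batch effect. These counts therefore do not show how often camera calls lists of genes that move together. The interaction test recovered 69 of 200 simulated genes and called 8 unchanged ones.

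Work was done in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9) and R 4.3.3 (limma 3.58.1). Where a class had 0 nuclei in a library before and after the doublet calls, the upper limit is that of 3 counts, which covers counting error only.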

Results

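Few genes differed between the groups, and the lists that did so rest on 1 choice of test. With edgeR, 0 genes passed the threshold in 12 of the 13 classes and in whole libraries, and 1 gene passed in ependymal nuclei. Before adjustment, most classes and whole libraries had fewer genes with a small p than chance alone would give. Inhibitory neurons, oligodendrocyte precursors and choroid plexus nuclei had slightly more. The fit held no batch term, so differences between batches entered its error and can lower these counts. They are therefore no clean comparison with chance. Of 96 list and class combinations, 38 passed with camera at the preset correlation, 17 of them higher and 21 lower in ANGPT2 libraries. With sex as a covariate 9 were higher and 22 lower, and with block and sex together 4 and 20. Of the 38, 4 kept their call in every other setting tried at that correlation, and all 4 were lower. These were interferon response and antigen presentation genes in microglia, antigen presentation genes in oligodendrocytes and ribosomal protein genes in excitatory neurons. Among the 91 combinations that could be tested in every split of the libraries, the real split gave 37, and 5 of 35 splits gave at least as many. With a correlation estimated per list, and with fry, 0 of the 96 passed. Every list result below holds at the preset correlation only.

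The libraries matched their labels for sex. Females had 26864 to 48315 UMIs of Xist and males had 0 to 20, while Ddx3y had 0 UMIs in females and 657 to 2340 in males. Angpt2 was not detectably higher in ANGPT2 libraries. Whole libraries held 325, 271 and 97 Angpt2 UMIs in controls and 281, 229, 52 and 80 in ANGPT2 libraries, a log2 change of -0.19 (SE 0.25, adjusted p = 1), with 0.02 in batch 1 and -0.47 in batch 2. Endothelial nuclei held 6 Angpt2 UMIs in all in each group, which is 23.3 CPM in controls and 12.5 in ANGPT2 libraries, too few to compare. The values count the mouse gene, and a vector sequence outside the reference would not be counted. In whole libraries the receptor gene Tek had a log2 change of 0.68 (SE 0.30, unadjusted p = 0.0505) and the related gene Tie1 of 1.15 (SE 0.49, unadjusted p = 0.041), both with an adjusted p of 1. Over the settings tried Tek ran from 0.44 to 0.91 and Tie1 from 0.80 to 1.56. Endothelial nuclei also made up a larger share of ANGPT2 libraries (log2 ratio 0.49, adjusted p = 0.687 in edgeR), which raises endothelial genes in such sums.

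No gene passed the threshold in endothelial nuclei, and the lists that rose there lost their call in many settings. They included barrier transporters, basement membrane, the angiopoietin-Tie pathway and leukocyte adhesion, and tight junction genes as a list did not pass. Of 21 other settings, the call was lost in 10 for transporters, 7 for basement membrane, 12 for angiopoietin-Tie and 16 for leukocyte adhesion genes. Mitochondrially encoded (adjusted p = 0.0251 with camera) and ribosomal protein genes (0.0286) rose in these nuclei too. Each library had 41 to 117 endothelial nuclei with 42383 to 221383 UMIs. Of 2660 genes tested, 0 passed in edgeR and 0 in DESeq2, with 67 at an unadjusted p under 0.05. In simulated data built from these counts the test recovered 18 of 100 genes changed 2-fold, so changes of that size would mostly be missed.

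Barrier transporter genes rose (median log2 change 0.27, adjusted p = 0.0191, and 0.717 with an estimated correlation), with 15 of 18 tested members higher. Their score was 9.22 ± 0.0263 in controls (SD, n = 3) and 9.46 ± 0.123 in ANGPT2 libraries (SD, n = 4), and all 4 ANGPT2 libraries lay above every control (exact permutation p = 0.0571). The score differed by 0.21 in batch 1 and 0.29 in batch 2. The transporter list did not pass without the control female of batch 1 (adjusted p = 0.071), the ANGPT2 male of batch 1 (0.181) or the ANGPT2 female of batch 2 (0.231). It also missed the threshold at the higher clustering resolution (0.0801) and with doublets kept (0.604). Its members with the smallest p included Slc16a1, with a log2 change of 1.38 (SE 0.59, adjusted p = 1). Over the settings tried this value ran from 0.57 to 2.47, and 1 ANGPT2 library, the male of batch 2, had 516 CPM, against 120.3 to 179 in the other 3.

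The angiopoietin-Tie list rose (median 0.35, adjusted p = 0.0254, and 0.717 with an estimated correlation), and all 10 tested members were higher. Its score differed by 0.06 in batch 1 and 0.56 in batch 2 (exact permutation p = 0.171). With the replicate block its adjusted p was 0.0772. Without the control male of batch 1 it was 0.0724, without the control female of batch 1 it was 0.0802, and without the ANGPT2 female of batch 2 it was 0.35. Tek had a log2 change of 0.49 (SE 0.34), with 0.21 to 0.76 over the settings tried, and Tie1 of 0.38 (SE 0.33), with 0.22 to 0.46. Leukocyte adhesion genes rose (median 0.30, adjusted p = 0.0449, and 0.717 with an estimated correlation), with all 6 tested members higher and score differences of 0.38 and 0.26 by batch. This list had an adjusted p of 0.0841 with the block, and it missed the threshold without any of 5 libraries. These were the control male and female of batch 1 (0.164 and 0.332), the ANGPT2 males of batch 1 and batch 2 (0.053 and 0.0917) and the ANGPT2 female of batch 2 (0.0602). Basement membrane genes rose (median 0.25, adjusted p = 0.0232, and 0.717 with an estimated correlation) but differed by -0.13 in batch 1 and 1.08 in batch 2. Leaving out the control male of batch 2 (adjusted p = 0.377), the ANGPT2 male of batch 2 (0.0711) or the ANGPT2 female of batch 2 (0.199) ended that call, as did block and sex together (0.123) and keeping doublets (0.570).

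**Figure D1:**
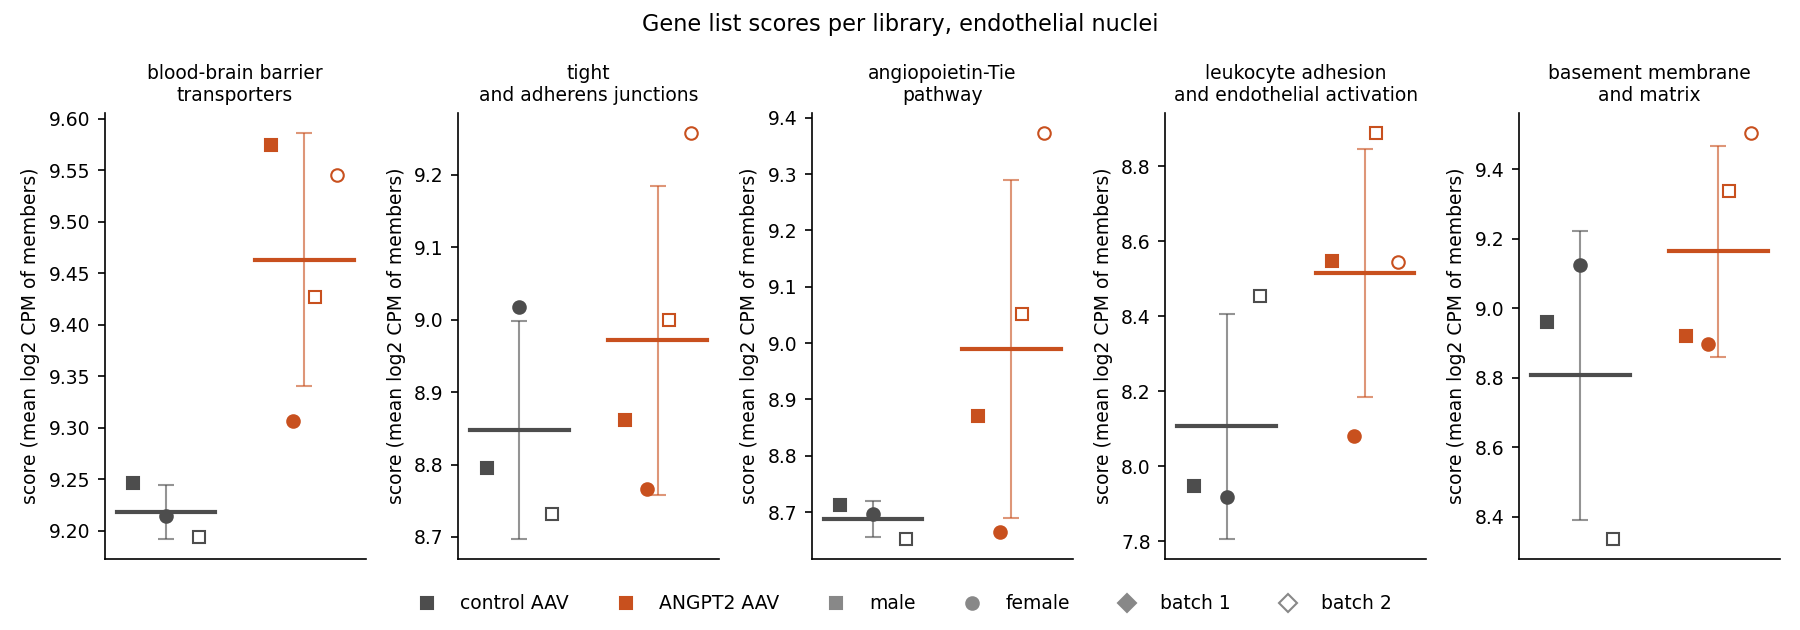
List scores in endothelial nuclei (vertical axes, mean log2 CPM of the members) for each library of the control and ANGPT2 groups, 1 point per library (squares males, circles females, filled batch 1, open batch 2), with bars for group means and whiskers of 1 SD. Barrier transporter scores of all 4 ANGPT2 libraries lie above every control, while junction scores overlap (adjusted p = 0.479).

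Tight and adherens junction genes did not pass (adjusted p = 0.479), with 6 members higher and 6 lower. Their median was -0.01 and their mean 0.10, with the test pointing up; without the ANGPT2 female of batch 2 it pointed down (0.919), and it did so with doublets kept (0.486). Adjusted over the list alone, 1 junction gene passed and 0 over all genes tested, and this gene was Cldn5. Cldn5 (chromosome 16, 18776847 to 18778262) had 359 ± 155 CPM in controls (SD, n = 3) and 1008 ± 510 in ANGPT2 libraries (SD, n = 4). Its log2 change was 1.39 (SE 0.41, unadjusted p = 0.00317, adjusted p = 1), with 0.46 in batch 1 and 2.64 in batch 2, and all 4 ANGPT2 libraries lay above every control. Phactr2 had the smallest p (1.32, SE 0.36), and Spock2 and Cxcl12 had values of 0.74 (SE 0.28) and 0.89 (SE 0.35). With doublets kept, Cldn5 was 0.47, Spock2 0.18 and Cxcl12 -0.14. Caveolae and vesicle transport genes (adjusted p = 0.458) and the Wnt pathway (0.285) did not pass, although the Wnt list did without the control male of batch 1 (0.0476). The lowest values by rank of p included Cldn11 (-1.49, SE 0.51), an oligodendrocyte gene, and Nlgn1 (-0.80, SE 0.28), a neuronal one, and with doublets kept these were -0.94 and -0.01. Interferon and antigen presentation genes were too few for a list test in endothelial nuclei.

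Mural nuclei showed no detectable difference in pericyte identity or basement membrane genes. There were 22 to 94 such nuclei per library, and of 1120 genes tested 0 passed in edgeR and 0 in DESeq2, with 29 at an unadjusted p under 0.05. Pericyte identity had an adjusted p of 0.768 (median -0.02, mean 0.02, test down), and its direction was up without the control male of batch 1 (0.861) or the ANGPT2 female of batch 2 (0.615). Basement membrane genes had an adjusted p of 0.937 (median 0.03, mean -0.04, test down), and their direction turned without any of 5 libraries. These were the control female of batch 1 (0.724), the ANGPT2 male (0.747) and female (0.74) of batch 1, the control male of batch 2 (0.906) and the ANGPT2 female of batch 2 (0.766). The genes with the smallest p were Epha6 (log2 change -1.17, SE 0.32) and Tmem30a (-1.05, SE 0.32).

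Microglia of ANGPT2 libraries had fewer transcripts of interferon response and antigen presentation genes. Homeostatic microglial genes rose slightly, while disease-associated, lysosomal and complement lists did not pass. Each library had 225 to 604 microglia with 270543 to 1112545 UMIs. Of 9080 genes tested, 0 passed in edgeR and 0 in DESeq2, with 345 at an unadjusted p under 0.05. With block and sex together 10 genes passed, and with sex alone 3. In edgeR, 10 genes also passed without the control male of batch 2, and 1 without the control male of batch 1.

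All 17 tested interferon response genes were lower (median log2 change -0.80, mean -0.86, adjusted p = 2.2e-24, and 0.432 with an estimated correlation). Of these, 14 passed when adjusted over the list alone, and 0 over all genes tested. The score was 6.09 ± 0.209 in controls (SD, n = 3) and 5.18 ± 0.529 in ANGPT2 libraries (SD, n = 4), a difference of -1.06 in batch 1 and -0.74 in batch 2. Of the 4 ANGPT2 libraries, 3 lay below every control and the female of batch 2, at 5.92, lay at the level of the lowest control (exact permutation p = 0.0857). The call held without each library in turn, with adjusted p of at most 1.1e-13. Sp100 (-0.84, SE 0.19, adjusted p = 0.364) was among the members with the smallest p. Ifi207 (-1.46, SE 0.34) belongs to a family of close paralogs, so its value is uncertain.

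**Figure D2:**
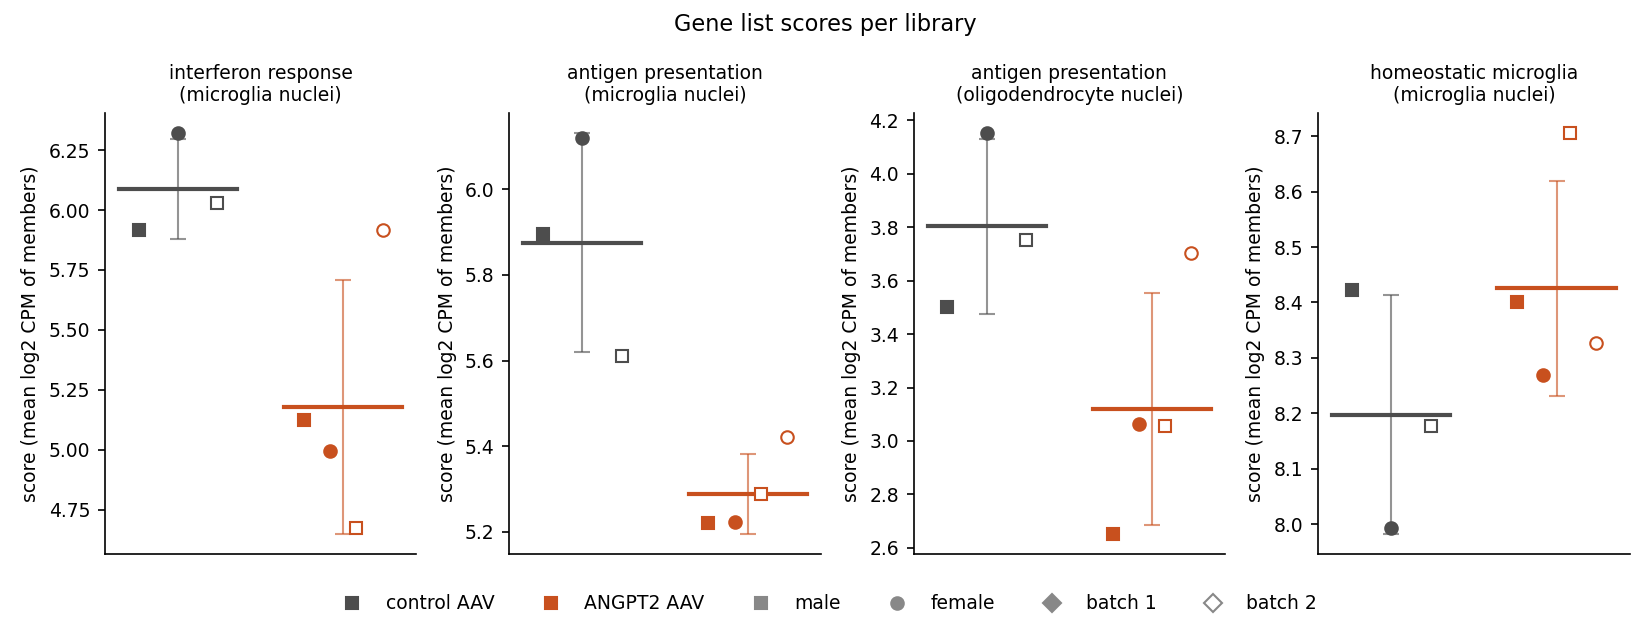
List scores (vertical axes, mean log2 CPM of the members) in microglia and oligodendrocyte nuclei for each library of the control and ANGPT2 groups, 1 point per library (squares males, circles females, filled batch 1, open batch 2), with bars for group means and whiskers of 1 SD. Interferon scores of 3 of the 4 ANGPT2 libraries lie below every control, and the female of batch 2 lies at 5.92.

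Antigen presentation genes fell in microglia (median -0.77, adjusted p = 1.1e-08, and 0.432 with an estimated correlation), with 9 of 11 tested members lower. All 4 ANGPT2 libraries lay below every control (exact permutation p = 0.0286, the smallest this design can give), with score differences of -0.79 in batch 1 and -0.26 in batch 2. Adjusted over the list alone, 5 members passed, and 0 over all genes tested. The call held without each library in turn, with adjusted p of at most 0.000166. Nlrc5 (chromosome 8, 94434356 to 94527272) had a log2 change of -1.55 (SE 0.32, adjusted p = 0.251), with -1.55 in batch 1 and -1.58 in batch 2. H2-D1 (chromosome 17, 35262730 to 35267499) had -1.07 (SE 0.24), with -1.31 in batch 1 and -0.07 in batch 2, and H2-K1 had -0.98 (SE 0.28), with -1.27 to -0.61 over the settings tried. H2-Q7 (-2.19, SE 0.42) and H2-Q4 (-1.77, SE 0.37, with -2.04 to -1.17 over the settings) are close paralogs, and their separate values are uncertain.

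Homeostatic genes rose in microglia (median 0.22, adjusted p = 7.4e-05, and 0.717 with an estimated correlation), with 18 of 20 members higher and score differences of 0.13 and 0.34 by batch (exact permutation p = 0.286). Without the control female of batch 1 the adjusted p was 0.0627. Disease-associated microglia genes did not pass (median -0.05, adjusted p = 0.255), with 10 members higher and 19 lower. They passed, lower, without the control male of batch 1 (0.0475) or the ANGPT2 female of batch 2 (0.00793), and with block and sex together (0.0289). Adjusted over the list alone, 1 of these genes passed, Cybb (-1.26, SE 0.31, with -1.41 to -0.83 over the settings), and 0 over all genes tested. Inflammatory cytokine genes did not pass (0.167), except without the ANGPT2 male of batch 1 (0.00804), the control male of batch 2 (0.0212) or the ANGPT2 female of batch 2 (0.0128). Cholesterol synthesis (0.479), complement (0.768) and lysosome (0.931) lists did not pass either. For complement the median was -0.00 and the mean 0.02 with the test up, and for lysosome both were -0.01 with the test up. The complement direction turned without the control male (0.865) or the ANGPT2 male (0.996) of batch 2, and the lysosome direction without the control female of batch 1 (0.619) or the ANGPT2 female of batch 2 (0.801). Outside the lists, Lypd6 (log2 change 2.00, SE 0.36, adjusted p = 0.251) and Col6a3 (1.82, SE 0.46) were among the higher genes with the smallest p, and Skap1 (-1.92, SE 0.39) and Hip1 (-1.06, SE 0.22) among the lower ones. Skap1 is a fixed lymphocyte marker.

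Nuclei carrying lymphocyte markers grouped with the microglia at the first clustering resolution, and fewer were seen in ANGPT2 libraries. At the higher clustering resolution 1 cluster was named for lymphocytes, and it held 16, 19 and 6 kept nuclei in the control libraries and 3, 8, 0 and 4 in the ANGPT2 libraries (difference -0.128 points of kept nuclei, exact permutation p = 0.0571, and 0.111 when permuting within the batch). Nuclei with at least 3 such markers in the microglia class numbered 17, 17 and 4 in the control libraries and 2, 4, 0 and 1 in the ANGPT2 libraries. They made up 0.161% ± 0.102 of kept nuclei in controls (SD, n = 3) and 0.0215% ± 0.0195 in ANGPT2 libraries (SD, n = 4). The difference of -0.140 points had an exact permutation p of 0.0571, and was -0.183 in batch 1 and -0.0386 in batch 2. Permuting within the batch gave a p of 0.0556, the smallest it can give. After all libraries were thinned to 1 median depth, 19 such nuclei were left in controls and 4 in ANGPT2 libraries. The difference was then -0.0675 (exact permutation p = 0.0286, and 0.0556 when permuting within the batch). Among oligodendrocytes, which should lack these markers, 1 nucleus in the control female of batch 1 had at least 3 of them. A single lymphocyte marker UMI was seen in 2.15% to 9.28% of microglia (median depth 808 to 2749 UMIs) and in 1.90% to 7.42% of oligodendrocytes (808 to 2814 UMIs), so single UMIs are largely background. Both counts of nuclei were chosen after the data were seen.

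Oligodendrocytes of ANGPT2 libraries had fewer antigen presentation and unfolded protein response transcripts. The disease-associated list also fell, on the strength of 1 control library, and myelin genes rose slightly. Each library had 821 to 1893 oligodendrocytes. Of 12424 genes tested, 0 passed in edgeR and 0 in DESeq2, with 307 at an unadjusted p under 0.05. Antigen presentation genes fell (median -0.72, adjusted p = 5.2e-06, and 0.613 with an estimated correlation), with 6 of 7 tested members lower and score differences of -0.97 and -0.37 by batch (exact permutation p = 0.0857). When adjusted over the list alone, 3 members passed, and 0 over all genes tested, and the call held without each library in turn. H2-D1 had a log2 change of -1.20 (SE 0.31, adjusted p = 1), with -1.57 in batch 1 and -0.05 in batch 2. Nlrc5 had -2.22 (SE 0.64) and H2-K1 had -1.25 (SE 0.41). Without the control female of batch 1, H2-D1, Nlrc5 and H2-K1 were -0.74, -1.26 and -0.61. Unfolded protein response genes fell (median -0.33, adjusted p = 0.000121, and 0.639 with an estimated correlation), with 9 of 10 members lower and Hspa5 at -0.38 (SE 0.14). Their score was lower in all 4 ANGPT2 libraries than in every control (exact permutation p = 0.0286), by -0.35 in batch 1 and -0.22 in batch 2. The call held without each library in turn, but not with males only (0.120), with the batch block on males (0.0914) or with block and sex without the control female of batch 1 (0.130).

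The disease-associated oligodendrocyte list fell (median -0.30, adjusted p = 1.9e-05, and 0.717 with an estimated correlation), with 15 of 17 members lower, but by batch the score differed by -0.64 and 0.13. Without the control female of batch 1 the adjusted p was 0.206. Of the members, 2 passed when adjusted over the list alone, and 0 over all genes tested. C4b had a log2 change of -1.33 (SE 0.40) and Serpina3n of -1.76 (SE 0.67), and without the control female of batch 1 these were -0.55 and -0.03. Myelin genes rose (median 0.07, adjusted p = 0.0233, and 0.717 with an estimated correlation) but not without the control female of batch 1 (0.369), the control male of batch 2 (0.11) or the ANGPT2 male of batch 2 (0.329). Interferon genes fell in oligodendrocytes too (median -0.33, adjusted p = 0.0233, and 0.717 with an estimated correlation), with score differences of -0.35 and -0.24 by batch. That call ended without the control female of batch 1 (0.389), the ANGPT2 male (0.0536) or female (0.175) of batch 1, or the control male (0.091) or ANGPT2 male (0.0815) of batch 2. Cholesterol synthesis genes fell (median -0.10, adjusted p = 0.0402, and 0.717 with an estimated correlation), with score differences of -0.11 and -0.19 by batch. Their call ended without the control male (0.075), control female (0.0589) or ANGPT2 female (0.183) of batch 1, or the control male (0.235) or ANGPT2 male (0.0633) of batch 2. Marcks had a log2 change of 0.55 (SE 0.16), and Sema3d (-1.11) and Col14a1 (-1.41) had the smallest p among lower values.

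Astrocytes had lower values of reactive genes in ANGPT2 libraries, but the difference rested on 1 control library. Each library had 220 to 665 astrocytes. Of the 2 clusters in this class, the smaller made up 37.9% of pooled nuclei in controls and 26.8% in ANGPT2 libraries. Values for the class therefore mix expression with make-up. Of 9625 genes tested, 0 passed in edgeR and 0 in DESeq2, with 330 at an unadjusted p under 0.05. Disease-associated astrocyte genes fell (median -0.29, adjusted p = 0.00433, and 0.717 with an estimated correlation), with 13 of 14 members lower and score differences of -0.48 and -0.28 by batch. Without the control female of batch 1 the adjusted p was 0.762, without the ANGPT2 female of batch 1 it was 0.0708, and with males only it was 0.248. Pan-reactive genes fell (mean -0.99, adjusted p = 0.0135, and 0.717 with an estimated correlation), with all 6 lower and score differences of -1.0 and -0.32 by batch. This list turned upward without the control female of batch 1 (0.779), and its adjusted p was 0.183 without the ANGPT2 female of batch 1. Gfap had a log2 change of -1.07 (SE 0.47) and Vim of -1.52 (SE 0.74), and without the control female of batch 1 these were -0.06 and 0.60. Unfolded protein response genes fell (median -0.33, adjusted p = 0.00519, and 0.639 with an estimated correlation), by -0.35 and -0.17 in score by batch, but had an adjusted p of 0.0968 without that control. Antigen presentation genes missed the threshold in astrocytes (median -0.36, adjusted p = 0.0516). They passed without the control male of batch 1 (0.0161), without the ANGPT2 female of batch 2 (0.0316) and with the replicate block (0.0478). Interferon (0.504), endfoot (0.638) and cholesterol synthesis (0.931) lists did not pass. The endfoot direction turned without the ANGPT2 female of batch 2 (0.766). The cholesterol list passed, lower, without the control female of batch 1 (0.000565) and, higher, without the control male of batch 2 (0.0212), and its direction turned without the control male (0.696) or ANGPT2 male (0.646) of batch 1 or the ANGPT2 female of batch 2 (0.655). Fgf13 had a log2 change of 0.71 (SE 0.16) and Stk32a of -1.63 (SE 0.41), both with an adjusted p of 0.993, and Stk32a ran from -2.07 to -1.06 over the settings.

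In neurons the largest difference, in activity-regulated genes, came from 1 control library. Stress-response and ribosomal protein genes fell in excitatory neurons and did so without each library in turn, but stress-response genes did not pass with males only. Of 17694 genes tested in excitatory neurons, 0 passed in edgeR and 0 in DESeq2, with 782 at an unadjusted p under 0.05. Activity-regulated genes fell in excitatory neurons (median -1.32, adjusted p = 2.1e-09, and 0.717 with an estimated correlation), with 22 of 23 members lower and score differences of -1.02 and -0.40 by batch. The score of the control female of batch 1 was 5.57, and the other 6 libraries had 2.74 to 3.55. Without that library the direction turned upward (adjusted p = 0.724). Npas4 had a log2 change of -3.36 (SE 1.01) and Nptx2 of -2.61 (SE 0.89), and without it these were -0.20 and 0.20. In inhibitory neurons the list fell too (median -1.08, adjusted p = 1.9e-07, and 0.717 with an estimated correlation) with score differences of -0.80 and -0.50 by batch, and its adjusted p was 0.639 without that library. Adjusted over the list alone, 2 of its genes passed in inhibitory neurons, and 0 over all genes tested.

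**Figure D3:**
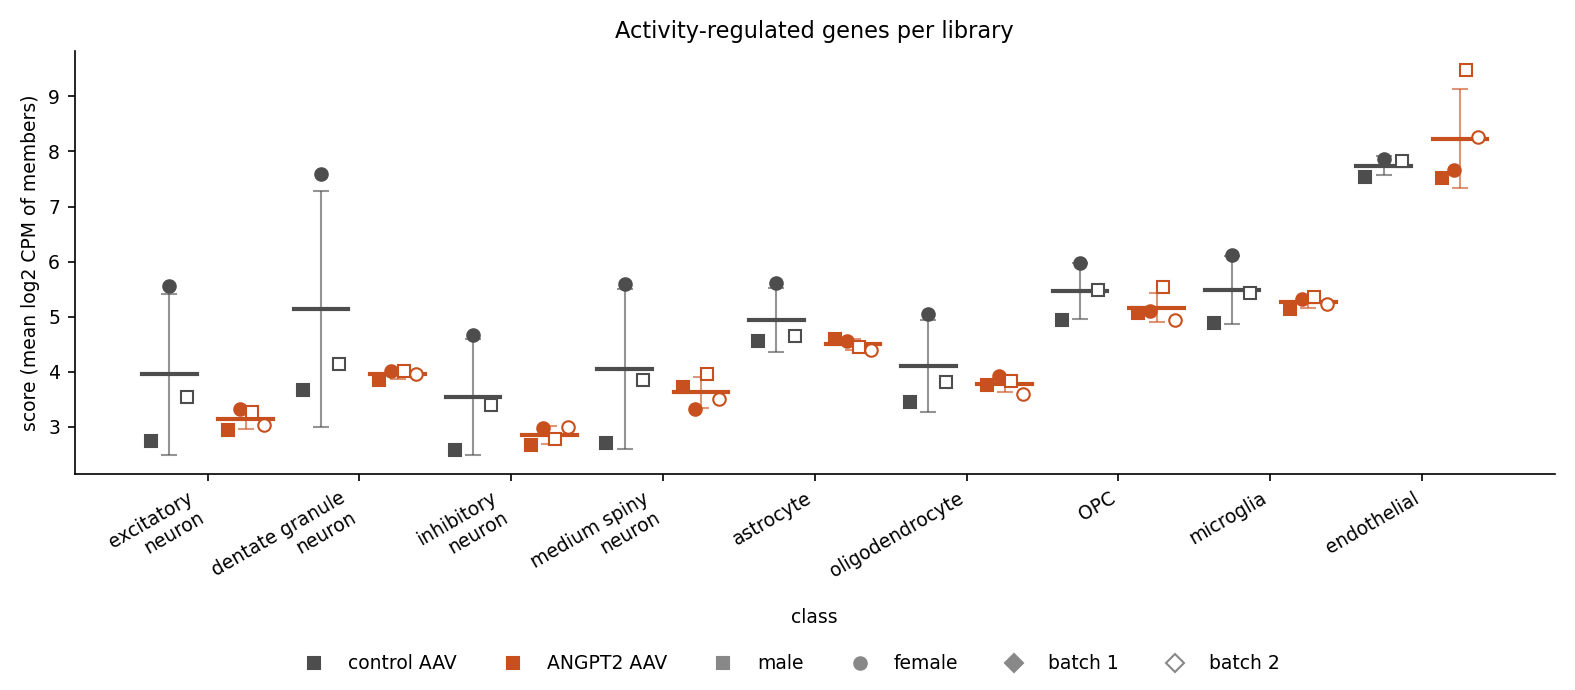
Scores of activity-regulated genes (vertical axis, mean log2 CPM of the members) by class (horizontal axis) for each library of the control and ANGPT2 groups, 1 point per library (squares males, circles females, filled batch 1, open batch 2), with bars for group means and whiskers of 1 SD. In excitatory neurons the control female of batch 1 lies at 5.57 and the other libraries lie between 2.74 and 3.55.

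Ribosomal protein genes fell in excitatory neurons (median -0.26, adjusted p = 3.2e-06, and 0.717 with an estimated correlation), with all 26 lower, but the score differed by -0.02 in batch 1 and -0.56 in batch 2. Excitatory nuclei of batch 2 had a median of 3740 UMIs in the control male and 7963 and 5457 in the ANGPT2 male and female. Thalamic neurons made up 0.402% of the ANGPT2 male of batch 2 and 8.50% of that of batch 1. Dentate granule neurons made up 9.51% of the control female and 1.13% of the ANGPT2 female of batch 1. Values for the excitatory class therefore mix expression with make-up. Unfolded protein response genes fell (median -0.29, adjusted p = 0.00167, and 0.717 with an estimated correlation), by -0.29 and -0.18 in score by batch. They did not pass with males only (0.198), with the batch block on males (0.164) or with block and sex without the control female of batch 1 (0.189). Heat shock genes fell (median -0.29, adjusted p = 0.00284, and 0.717 with an estimated correlation), by -0.32 and -0.62, but not with males only (0.0948) or with the batch block on males (0.0703). Adjusted over the list alone, 1 heat shock gene passed, and 0 over all genes tested. The synapse list did not pass in excitatory neurons (0.15), except without the control female (0.00951) or the ANGPT2 female (0.0407) of batch 1. Otof had a log2 change of 0.88 (SE 0.19, with 0.57 to 1.02 over the settings) and Tox4 of -0.46 (SE 0.11), both with an adjusted p of 0.887.

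Of 13580 genes tested in inhibitory neurons, 0 passed in edgeR, with 788 at an unadjusted p under 0.05, while DESeq2 called 24, of which 23 were higher. Without the control female of batch 1 edgeR called 4, and without the control male of batch 2 it called 1. The genes with the smallest p in edgeR were Egfr (log2 change 0.96, SE 0.13), Fmn1 (0.65, SE 0.10, adjusted p = 0.186) and Zfp423 (-0.68, SE 0.13). The class differed in its clusters: 1 cluster made up 55.8% of it in controls and 33.7% in ANGPT2 libraries, and another made up 38.1% in ANGPT2 libraries. Values for the class therefore mix expression with the kinds of inhibitory neuron sampled. Unfolded protein response genes fell in this class (median -0.26, adjusted p = 0.0178, and 0.717 with an estimated correlation), with all 4 ANGPT2 scores below every control (exact permutation p = 0.0286) and differences of -0.35 and -0.23 by batch. That call ended without the control female (0.229), the ANGPT2 male (0.0999) or the ANGPT2 female (0.149) of batch 1. Synapse genes rose slightly (median 0.08, adjusted p = 0.0449, and 0.717 with an estimated correlation), by 0.03 and 0.13 in score by batch, with an adjusted p of 0.0949 with the replicate block. Their call ended without the control male (0.57) or ANGPT2 male (0.0564) of batch 1, or the control male (0.142), ANGPT2 male (0.0509) or ANGPT2 female (0.255) of batch 2. In medium spiny neurons, of 11231 genes tested, 0 passed in edgeR, with 179 at an unadjusted p under 0.05, and DESeq2 called 1. With nuclei pooled over libraries, the leading cluster made up 80.6% of this class in controls and 61.8% in ANGPT2 libraries. Another made up 27.5% in ANGPT2 libraries, but of its 961 nuclei, called doublets included, 774 came from the ANGPT2 male of batch 2. Of the 1742 control nuclei of the class, 1608 came from the control male of batch 2. The control male of batch 1 had 10 such nuclei. Values of this class thus mix expression with make-up too, and the pooled shares largely reflect single libraries. Without the control male of batch 2 edgeR called 7. The DESeq2 gene, Dusp14 (log2 change -2.05 and adjusted p = 0.0357 in DESeq2), was chosen after its values were seen. Ribosomal protein genes fell there (median -0.05, adjusted p = 0.0191, and 0.717 with an estimated correlation), but not without the control male of batch 1 (0.275) or the ANGPT2 female of batch 2 (0.94), with differences of -0.16 and -0.20 by batch.

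Oligodendrocyte precursors (OPC), fibroblasts, ependymal and choroid plexus nuclei had few differences. In OPC, of 8602 genes tested, 0 passed in edgeR and 0 in DESeq2, with 440 at an unadjusted p under 0.05. H2-K1 in OPC had a log2 change of -1.68 (SE 0.38) and Cenpp of 1.34 (SE 0.31), both with an adjusted p of 0.878, and with block and sex Cenpp had 0.00995. Over the settings Cenpp ran from 0.48 to 1.57. In OPC, 2 genes passed without the control female of batch 1, and 1 without the control male of batch 2. The OPC identity list did not pass (0.175), except without the ANGPT2 female of batch 1 (0.0122). OPC ribosomal protein genes fell (median -0.12, adjusted p = 0.0285, 0.101 with the replicate block, and 0.717 with an estimated correlation), with score differences of 0.08 and -0.58 by batch. Their call ended without the control female of batch 1 (0.0692), or the control male (0.188), ANGPT2 male (0.102) or ANGPT2 female (0.751) of batch 2. Committed precursors had 0 of 3345 genes past in edgeR and 0 in DESeq2, with 93 at an unadjusted p under 0.05. Fibroblasts had 0 of 2911 past in edgeR and 0 in DESeq2, with 113 at an unadjusted p under 0.05 and Adamtsl1 lowest by rank of p (-2.09, SE 0.48). In choroid plexus nuclei, of which the doublet calls left too few in batch 2 for a test (2 control and 2 ANGPT2 libraries of batch 1 remained), 0 of 5217 passed in edgeR and 0 in DESeq2, with 275 at an unadjusted p under 0.05. Leaving out a library gave 13 genes (control male), 17 (control female), 40 (ANGPT2 male) or 2 (ANGPT2 female), with 1 library left in that arm.

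In ependymal nuclei Gpc5 fell (log2 change -2.79, SE 0.54, adjusted p = 0.0313), with -2.39 in batch 1 and -2.13 in batch 2, the single gene of 3108 past the threshold in edgeR, where 128 had an unadjusted p under 0.05. Gpc5 (chromosome 14, 115092215 to 116525179) had 687 ± 653 CPM in controls (SD, n = 3) and 98.0 ± 64.5 in ANGPT2 libraries (SD, n = 4). The control males of batch 1 (1394 CPM) and batch 2 (557 CPM) lay above every ANGPT2 library. The control female had 108 CPM, within the ANGPT2 range and below the ANGPT2 female of batch 1 (165 CPM). The difference therefore rests on the control males. Gpc5 is a fixed marker of astrocytes, and DESeq2 called 0 genes here. Genes past the threshold numbered 4 without the control female of batch 1, 5 without the control male of batch 2 and 0 without the control male of batch 1 or any of the 4 ANGPT2 libraries. The log2 change of Gpc5 shrank to -1.51 without the control male of batch 1 and to -1.26 with doublets kept. It was -2.31 without the ANGPT2 male of batch 1, and it stayed at -2.83 and -2.78 without the male and female of batch 2, where only the call was lost (adjusted p = 0.119 and 0.157 in edgeR). Heat shock genes fell in ependymal nuclei (median -0.35, adjusted p = 0.0402, and 0.717 with an estimated correlation), by -0.17 and -0.65 in score by batch. Without the ANGPT2 male (0.125) or female (0.0534) of batch 1, or the control male (0.597) or ANGPT2 female (0.0671) of batch 2, that call ended.

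Mitochondrially encoded transcripts rose in 9 classes, but the difference did not hold across batches. The largest was in choroid plexus nuclei (median 1.09, adjusted p = 1.2e-07, and 0.717 with an estimated correlation), where 8 of 11 genes passed adjusted over the list alone and 0 over all genes tested. In mural nuclei (median 0.36, adjusted p = 0.00284, and 0.717 with an estimated correlation) the score differed by 0.67 in batch 1 and -0.39 in batch 2. Of the 9 classes, 0 kept the call without the ANGPT2 female of batch 1 (mural adjusted p = 0.147, choroid plexus 0.566), and 1 kept it without the control male of batch 1 (mural 0.851). Without that control the direction turned in 6 classes. Without the ANGPT2 female of batch 2 the call ended in fibroblasts (0.241), astrocytes (0.255) and oligodendrocytes (0.0685). Of the 8 classes present in both batches, 1 (endothelial, 0.52 and 0.01) was higher in both. The ANGPT2 female of batch 1 also had the most free RNA by Ttr, a choroid plexus transcript, at 1632 CPM in microglia, where the other libraries had 96.2 to 469. In ependymal nuclei the mitochondrial list fell (median -0.19, adjusted p = 0.0285, 0.113 with the replicate block, and 0.717 with an estimated correlation), but not without the control female of batch 1 (0.786) or the ANGPT2 male of batch 2 (0.962). Endothelial ribosomal protein genes rose (median 0.21, adjusted p = 0.0286, and 0.729 with an estimated correlation), by -0.07 and 0.96 in score by batch. That call ended without the ANGPT2 female of batch 1 (0.267) or of batch 2 (0.688), and its direction turned without the control male of batch 2 (0.807). Hypoxia response and amyloid precursor protein processing genes passed in no class in which they were tested, with smallest adjusted p of 0.0743 in excitatory neurons and 0.208 in choroid plexus nuclei. The excitatory hypoxia list passed without the control male (0.0128) or ANGPT2 female (0.0358) of batch 1.

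Summed over whole libraries, plaque-induced genes were slightly lower. The list fell (median -0.20, adjusted p = 3.4e-05, and 0.717 with an estimated correlation), with 29 of 32 members lower and score differences of -0.32 and -0.15 by batch. Without the control female of batch 1 the adjusted p was 0.249, and without the ANGPT2 male of batch 1 it was 0.053. Of 19977 genes tested, 0 passed in edgeR, with 571 at an unadjusted p under 0.05, and DESeq2 called 1, Gm48530 (log2 change 0.89, adjusted p = 0.00366 in DESeq2), which was chosen after its values were seen. H2-Eb1 had a log2 change of -1.76 (SE 0.40, adjusted p = 1). Whole-library values mix expression with the make-up of each library.

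No class had a detectable difference in its share of nuclei. An edgeR test of nuclei per class called 0 of 13, with the smallest unadjusted p at 0.0829 and the smallest adjusted p at 0.687. The exact permutation test cannot give a p below 0.0286, so after adjustment over 13 classes no single class could pass, and its count of 0 carries little weight (smallest adjusted p 0.743). Endothelial nuclei made up 0.678% ± 0.128 in controls (SD, n = 3) and 0.952% ± 0.283 in ANGPT2 libraries (SD, n = 4; exact p = 0.2), with differences of 0.357 and 0.208 points by batch. Mural nuclei made up 0.437% and 0.686% (exact p = 0.229), fibroblasts 0.849% and 0.520% (exact p = 0.143), and inhibitory neurons 10.2% and 7.04% (exact p = 0.143). Microglia made up 5.54% and 4.70% (exact p = 0.571), astrocytes 5.14% and 5.68%, and oligodendrocytes 19.8% and 19.0%. Medium spiny neurons ranged from 0.119% to 29.4% of a library. Choroid plexus nuclei in batch 2 numbered 18 in the control male, 0 in the ANGPT2 male and 12 in the ANGPT2 female before called doublets were removed, and 1, 0 and 0 after. The 0 of 5974 in the ANGPT2 male allows a share of up to 0.0502%.

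**Figure D4:**
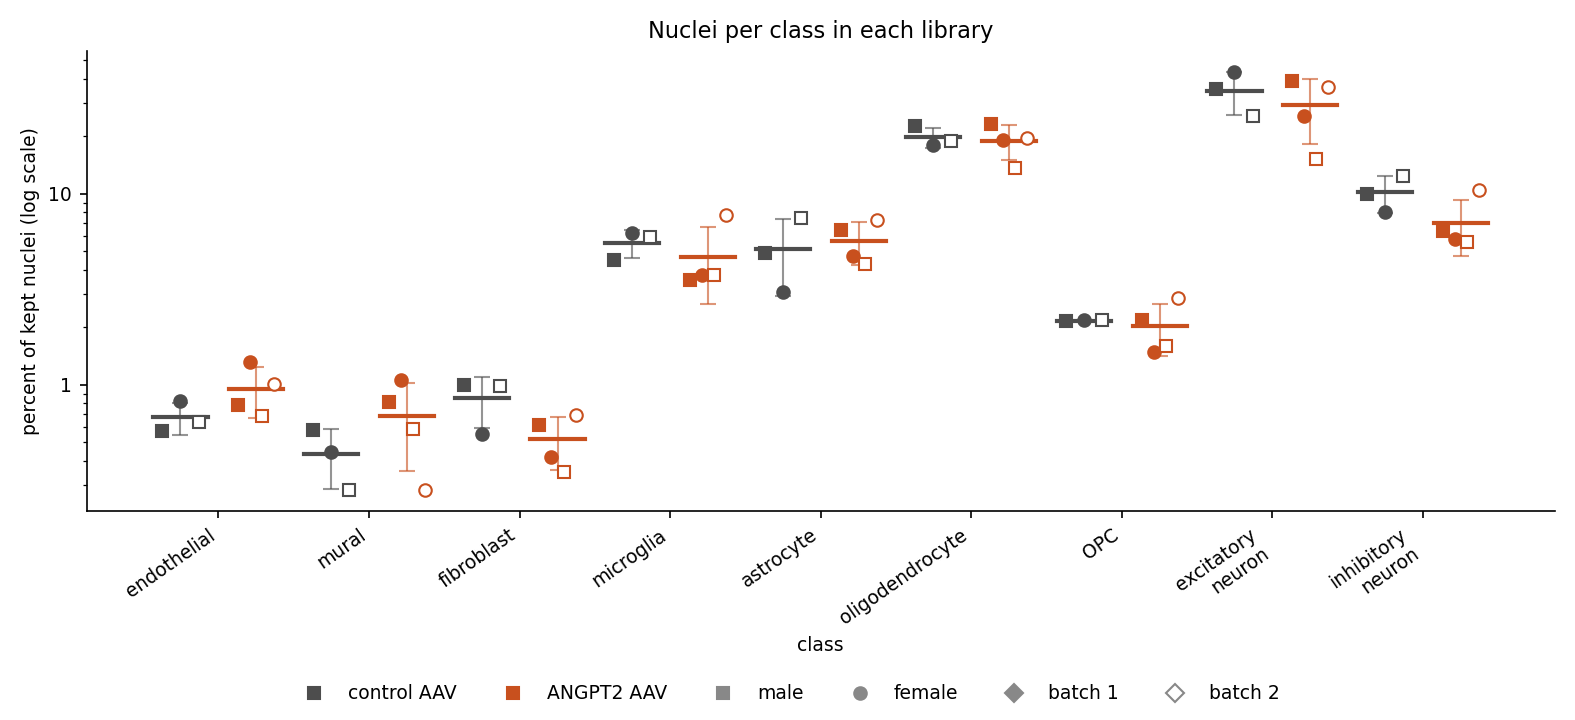
Percent of kept nuclei (vertical axis, log scale) by class (horizontal axis, without medium spiny neurons) for each library of the control and ANGPT2 groups, 1 point per library (squares males, circles females, filled batch 1, open batch 2), with bars for group means and whiskers of 1 SD. Endothelial nuclei average 0.678% in controls and 0.952% in ANGPT2 libraries, with an exact permutation p of 0.2.

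Whether the effect of ANGPT2 differs between the sexes cannot be read from these libraries, since there is 1 control female. With edgeR the interaction term passed for 7 genes in excitatory neurons, 6 in OPC, 2 in medium spiny neurons, 1 in ependymal nuclei and 1 in whole libraries. Nptx2 and Npas4 in excitatory neurons were among them, with interaction values of -4.20 and -4.46. Nptx2 had 131 CPM in the control female and 6.74 to 8.89 in the other 6 libraries, ANGPT2 females included. In astrocytes, committed precursors, endothelial nuclei, fibroblasts, inhibitory neurons, microglia, mural nuclei and oligodendrocytes 0 genes passed in edgeR, with 270, 169, 43, 109, 510, 239, 28 and 297 genes at an unadjusted p under 0.05. DESeq2 was not run for the interaction. With the replicate block the counts were 24 in excitatory neurons, 12 in OPC, 9 in astrocytes, 6 in fibroblasts, 3 in inhibitory neurons and 2 in microglia. They were 3 in medium spiny neurons, 1 in ependymal nuclei and 1 in whole libraries. The only control female is the library with the high activity scores.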

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

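The tests of explanations in this part and the counts over other splits of the libraries were chosen only after the results were seen, while the test of the sex interaction was fixed beforehand.

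Interferon response and antigen presentation genes were lower in microglia of ANGPT2 libraries. For the interferon list the tables argue against nuclei with markers of other immune cells (median log2 change -0.88 without them). They also argue against depth (-0.94 after thinning) and against the batches, since the score was lower in both (-1.06 and -0.74). The list stayed lower without each library in turn (camera adjusted p of at most 1.1e-13) and with the replicate block (5.3e-28). Those camera p-values do not measure the spread between mice, for which the score gave an exact permutation p of 0.0857. Genes that move together remain open (0.432 with an estimated correlation). After thinning 10 of the 17 interferon and 7 of the 11 antigen presentation genes could be tested, with medians over these same genes of -0.79 before and -0.94 after, and of -0.35 before and -0.48 after. For antigen presentation other immune nuclei stay open for part of the difference (median -0.77, and -0.60 without them), and depth stays open for the members lost in thinning. A lower interferon state of microglia under ANGPT2 and a difference between mice in that state, unrelated to the vector, both stay open with 7 libraries, of which the ANGPT2 female of batch 2 lay at the level of the controls.

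Activity-regulated genes were high in neurons of 1 control library, the female of batch 1, by 2.42 in excitatory score over the mean of the others. The tables argue against 1 dentate granule cluster as the source (excess 1.99 without it and a further neuron cluster), against brief handling at death alone (excess 2.33 in the members that respond late) and against a sex difference in both groups (ANGPT2 females minus males 0.0802). The excess was seen in inhibitory (1.77) and medium spiny neurons (2.08) and, smaller, in astrocytes (1.07) and microglia (0.89), but not in endothelial nuclei (-0.19). What raised these genes in that mouse was not tested, and a difference of control females cannot be excluded, because the study has 1 control female.

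Mitochondrially encoded transcripts were higher in 9 classes of ANGPT2 libraries. The tables argue against a difference that holds in each batch, since 1 of 8 classes was higher in both. Free RNA in the ANGPT2 female of batch 1 may account for part of it: 0 classes kept the call without that library. It had the highest Ttr in microglia, 1632 CPM, but also the largest share of choroid plexus nuclei (0.814%), so Ttr does not measure free RNA alone. The low level in the control male of batch 1 stays open beside free RNA, since without that control 1 class kept the call.

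Some libraries lay far from the other 3 of the ANGPT2 group, in 5 of 101 groups of 4 checked, and chance does this in about 1 in 20 groups. In the female of batch 2 the pan-reactive astrocyte score was 5.67, against 4.19 to 4.43 in the others. Inhibitory neurons made up 10.4% of that library, against 5.57% to 6.36%. Microglia made up 7.75% of it, against 3.52% to 3.77%. In the male of batch 2 medium spiny neurons made up 29.4%, against 2.91% to 6.99%. Endothelial Slc16a1 was at 516 CPM in that male, against 120.3 to 179 in the others.

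The interaction term of treatment and sex passed in edgeR for the genes below, with the female minus the male log2 change given. The control females are 1 library, so no difference between the sexes in the effect of ANGPT2 can be read from these values. In ependymal nuclei Gpc5 had 5.11. In excitatory neurons the values were -4.20 for Nptx2, -3.49 for Ptgs2, -2.62 for Mir670hg, -3.10 for Tll1, -4.46 for Npas4, -2.08 for Zmiz1 and -2.93 for Plekha2. In medium spiny neurons they were -5.34 for Npas4 and -3.61 for Junb, and in whole libraries -4.05 for Nptx2. Junb did not pass with the replicate block (adjusted p = 0.0862 in edgeR). In OPC they were -3.26 for Ermard, -2.58 for Arhgap22, -2.32 for Fstl4, -2.06 for Pmepa1, -2.62 for Egr1 and -6.28 for Gm19299. That library is the one with the high activity scores, and apart from Gpc5 and Gm19299 it had the highest value of each gene. In excitatory neurons Ptgs2 had 101 CPM in it and 3.60 to 6.44 in the others, and in OPC Ermard had 203 against 16.2 to 31.3. Gm19299 had 72.6 to 117 CPM in the control female and the ANGPT2 libraries of batch 1, and at most 3.91 in the others, with 0 in the control male of batch 1.

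Other splits of the 7 libraries show whether chance can be excluded. The real split gave 37 list and class combinations among the 91 that could be tested in every split, 5 of 35 splits gave at least as many and the highest other gave 44, so chance cannot be excluded for the number of lists. For ependymal genes 14 of 35 splits gave at least the real 1, with 3 as the highest other. Where the real count was 0, every split gives at least as many (35 of 35), so the comparison says nothing about chance there. The highest other split then gave 289 genes in astrocytes, 524 in whole libraries, 79 in oligodendrocytes, 56 in excitatory neurons, 32 in inhibitory neurons, 32 in endothelial nuclei, 23 in OPC, 11 in microglia and 5 in mural nuclei. In each of these that split set the batches apart (3 libraries of batch 2 against 4 of batch 1), which points to a structure of the samples by batch, and with the replicate block these classes still had 0 genes. In medium spiny neurons the highest other split gave 26 and set the 3 males that are not the ANGPT2 male of batch 1 apart. In committed precursors it gave 12 and in fibroblasts 24, where the control male, ANGPT2 male and ANGPT2 female of batch 1 stood apart.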

How the results depend on the processing

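The settings without certain neuron clusters, with unnamed nuclei left out, with block and sex without the control female of batch 1, with the batch block on males, with microglia thinned or filtered, with excitatory neurons fitted in 3 parts, and every test of nuclei with lymphocyte markers were chosen after seeing the data. Over all settings, counts of genes per class were taken as unchanged in 221 comparisons and moved in 51. A count was unchanged if it stayed within 1.5 times its first value, or at 0 where that was 0. The first value was 0 in nearly every class, so the 221 mostly stand for counts that stayed at 0 and say little about stability. Counts of interaction genes stayed in 7 and moved in 6, and counts of list and class combinations stayed in 14 and moved in 7. List results were followed for 17 list and class combinations only, not for all 96 tested. These kept direction and side of the threshold in 259 comparisons, missed it in 86, newly passed in 3 and turned in 6. Of 63 genes named, 59 had the same direction in every setting 33 passed in at least 1, and the log2 change of 29 moved by over 1.5 times in at least 1. Shares of nuclei, those with lymphocyte markers included, kept their result in 70 comparisons, but this count carries little weight. Adjusted over 13 classes, the exact permutation test could hardly pass in any setting. The share of nuclei with lymphocyte markers passed after thinning (-0.0675, exact permutation p = 0.0286), but not when permuting within the batch (0.0556). It did not pass as the cluster named for lymphocytes at resolution 2 (-0.128). Counts moved in 0 classes at resolution 2, with at least 500 genes, with the replicate block, with RLE factors, without unnamed nuclei and without the neuron clusters. At resolution 2 a cluster of 944 nuclei with oligodendrocyte markers stayed unnamed, and 851 of these came from the control female of batch 1. The oligodendrocyte class of that setting therefore lacks them. For the changes below the cause was not tested unless one is named.

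With DESeq2, 0 genes passed in ependymal nuclei, 24 in inhibitory neurons, 1 in medium spiny neurons and 1 in whole libraries. With no filter on low counts, the counts were 27 in OPC, 47 in astrocytes, 11 in choroid plexus, 1 in committed precursors, 1 in endothelial nuclei, 5 in ependymal nuclei, 45 in inhibitory neurons, 23 in medium spiny neurons, 67 in microglia and 33 in oligodendrocytes, while leukocyte adhesion had an adjusted p of 0.964. With sex as a covariate, 8 choroid plexus and 3 microglia genes passed. With block and sex, 3 OPC, 2 astrocyte and 10 microglia genes passed, 24 list and class combinations, and the angiopoietin-Tie and leukocyte adhesion lists had 0.115 and 0.0548.

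With the estimated correlation 0 lists passed: interferon and antigen presentation in microglia had 0.432 each, and the angiopoietin-Tie, transporter and leukocyte adhesion lists 0.717 each. With fry 0 lists passed, with 0.454 for interferon and antigen presentation, 0.797 for the angiopoietin-Tie and leukocyte adhesion lists and 0.632 for transporters. With the replicate block the angiopoietin-Tie list had 0.0772 and leukocyte adhesion 0.0841. At resolution 2 the angiopoietin-Tie, transporter and leukocyte adhesion lists had 0.0623, 0.0801 and 0.0893. With at least 500 genes leukocyte adhesion had 0.0746. With doublets kept, Cxcl12 was -0.14 and junctions pointed down (0.486), the angiopoietin-Tie, transporter and leukocyte adhesion lists had 0.156, 0.604 and 0.269, and 0 ependymal genes passed.

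The unfolded protein response list in oligodendrocytes missed the threshold with males only (0.120), with the batch block on males (0.0914) and with block and sex without the control female of batch 1 (0.130).

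With males only, which leaves fewer libraries, Angpt2 was 0.0068, Nptx2 0.17 and Vim 0.35, all turned upward. The angiopoietin-Tie, transporter and leukocyte adhesion lists had 0.200, 0.209 and 0.118, 12 list and class combinations passed, and 1 microglia gene did, Mrc2, chosen after its values were seen. With the batch block on males, Nptx2 was 0.17 and Vim 0.36, and the excitatory activity list pointed up (0.709). The 3 endothelial lists had 0.164, 0.199 and 0.0705, 14 combinations passed, and the counts were 3 in OPC, 5 in ependymal nuclei, 1 in fibroblasts, 193 in inhibitory neurons, 4 in microglia, 4 in oligodendrocytes and 18 in whole libraries. With block and sex without the control female of batch 1, Nptx2 was 0.17 and Vim 0.45, and the excitatory activity list pointed up (0.862), since that library carries the high activity. The 3 endothelial lists had 0.189, 0.0792 and 0.189, 15 combinations passed, and the counts were 3 in OPC, 2 in ependymal nuclei, 4 in inhibitory neurons, 12 in medium spiny neurons and 4 in microglia. The interaction test with the block gave 12 genes in OPC, 9 in astrocytes, 24 in excitatory neurons, 6 in fibroblasts, 3 in inhibitory neurons and 2 in microglia.

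Leaving out each library in turn gave 25 to 37 list and class combinations. The counts of genes ran from 2 to 40 in choroid plexus (1 library is then left in an arm and is assumed to vary like the others), 0 to 2 in OPC, 0 to 5 in ependymal nuclei, 0 to 4 in inhibitory neurons, 0 to 7 in medium spiny neurons and 0 to 10 in microglia. The adjusted p ran from 0.00418 to 0.350 for the angiopoietin-Tie list, 0.0066 to 0.231 for transporters, 0.0214 to 0.332 for leukocyte adhesion and 0.246 to 0.919 for junctions, which turned without the ANGPT2 female of batch 2. It ran from 3.1e-34 to 0.724 for excitatory activity genes and 4.4e-10 to 0.779 for pan-reactive astrocyte genes, and both turned without the control female of batch 1. Nptx2 ran from -3.13 to 0.20 and Vim from -2.10 to 0.60, with the highest values without that library.

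The replicate block could not be fitted in choroid plexus nuclei, because the doublet calls left too few of them in batch 2. With doublets kept, 3 control and 3 ANGPT2 libraries entered that class, and 0 of 3098 genes passed. Fitted apart, dentate granule (10029 genes, 455 at an unadjusted p under 0.05), thalamic (13577 and 453) and other excitatory neurons (16766 and 897) had 0 genes past in edgeR, also without each library in turn. DESeq2 called 0, 0 and 2 genes in them. In simulated data edgeR recovered 18 of 100 endothelial genes changed 2-fold, 42 of 100 in mural nuclei and 58 of 100 in microglia.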

Other observations

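The tests of nuclei with lymphocyte markers were chosen only after the result was seen. Control libraries had 38 nuclei with at least 3 lymphocyte markers and ANGPT2 libraries 7, and the exact permutation p of their share was 0.0571. The cluster named for lymphocytes at resolution 2 held 41 kept nuclei in controls and 15 in ANGPT2 libraries (exact permutation p = 0.0571, and 0.111 when permuting within the batch). Fewer T or B cells in the brains of ANGPT2 mice may be a hypothesis for this. The tables argue against depth as the whole cause, since after thinning the share still differed by -0.0675 points. A shared origin with the lower interferon score of microglia cannot be told apart: over the 7 libraries, after removal of group means, Spearman's rho was 0.179 (exact permutation p = 0.713) and Pearson's r was 0.119 (exact permutation p = 0.771), and without the 2 libraries farthest from the median share r was -0.127. With so few nuclei and libraries no more can be read from them.

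The matrices hold 6311 to 9630 barcodes per library, while the labels give 900 to 1500 nuclei loaded without naming a volume or a library, so whether these numbers share a unit is not known. Unnamed clusters held 30.1% of the nuclei of the ANGPT2 female of batch 1 and 24.2% of those of the ANGPT2 male of batch 2, against 5.80% (ANGPT2 female of batch 2) to 16.97% (control male of batch 1) in the others.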
